A study of Mus musculus with 5 samples.

How the data were processed

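Gene expression was measured in mouse embryonic fibroblasts (MEFs) that lack Dicer, the enzyme that cuts double-stranded RNA into small RNAs, after transfection with small interfering RNA (siRNA). Total RNA was taken 48 hours after transfection, labelled with biotin and hybridised to Illumina BeadChips with 1 colour, per the labels. The knockdown group has 2 arrays, siTARBP2-1 (replicate 1) and siTARBP2-2 (replicate 2), with a different siRNA on each. The submitters' design text states that these siRNAs are independent. The control siRNA group has 3 arrays, siControl-1 to siControl-3; whether these are different siRNAs, separate cultures or repeats is not given in the sources used here, so what the spread between them measures is unknown. The labels call the cells MEFs and the controls siControl, while the submitters' design text speaks of metastatic cells and mock transfection; the labels were followed. Nothing in the sources used here says that the arrays come from separate cultures. The p-values of single genes therefore measure the spread between these samples, which may be technical.

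The deposited table of non-normalized signal holds 1 linear intensity and 1 detection p-value for each of 25697 probes and each array. The authors' processing notes name lumi and give no version; probe summary, scanner settings and genome build are not given in the sources used here. The deposited detection p-value columns of 4 arrays fell with their own signals, with a Spearman correlation of -0.961 to -0.967 across probes, and moved in steps of 1 in 798. The deposited column beside siTARBP2-2 had a Spearman correlation of 0.000598 with its signals and steps of 1 in 770, so it did not describe that array. It was replaced by the mean p-value of the other 4 arrays at the same signal rank, a choice made after the files were seen. The authors' series matrix holds quantile normalized intensities on a linear scale. Their lowest correlation with the same array's non-normalized signals was 0.9966, after centring each probe on the log2 scale. The target quantiles of the series matrix were near the mean of the 5 arrays and not equal to it, and the further steps are unknown. The authors' deposited table gives 1 log2 fold change for each of 18744 RefSeq accessions and a score of 1 for accessions it marks as higher. Its log2 values had a slope of 0.448 on the log2 ratio of the series matrix at log2 intensities of 5 to 7 and of 1.03 at 12 to 16, so it compresses changes of dim probes.

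The signals were background corrected and quantile normalized with neqc of limma 3.58.1 in R 4.3.3, with negative controls inferred from the detection p-values and an offset of 16, and taken to log2. Probes with a detection p under 0.05 on at least 2 arrays were kept, 13123 in all. The platform annotation gave 23978 probes 1 gene symbol, 0 probes several and 1719 probes none. Matching to RefSeq names of assembly GRCm38.p6 changed 0 symbols and left 11 genes without an entry; no coordinates are printed because the array's build is not stated. Of the kept probes 12341 named 8927 genes, and each of the 2416 genes with more than 1 kept probe was represented by the probe with the highest mean. Array medians of the raw signal ran from 79.0 to 81.9 and 12445 to 13051 probes per array were above background. The number of arrays limits the precision.

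Knockdown and control were compared with limma's lmFit and eBayes (two-sided), with Benjamini-Hochberg adjustment over all kept probes and a threshold of 0.05. A second limma fit gave each siRNA its own coefficient. Its spread comes from the 3 control arrays alone, with 2 residual degrees of freedom before moderation, and each lone siRNA array was assumed to vary like the controls. Gene lists fixed before the data were examined were tested with limma's camera at a preset correlation of 0.01. The cholesterol synthesis list, and so its counts, also held the fatty acid desaturases Scd1 and Scd2. The p-values were adjusted over the 17 lists with at least 5 measured genes. The lists were tested again with an estimated correlation and with fry. With an estimated correlation camera uses the residual degrees of freedom, 3 over both siRNAs and 2 in the fit of each siRNA. Hardly any list can pass with so few, so a call lost there decides little. Camera p-values at the preset correlation rest on the spread between genes, taken as nearly independent, and not on the spread between samples. For the interferon response list the estimated correlation was 0.804 over both siRNAs and 0.154 in the fit of each siRNA. For NF-kB and secreted inflammatory genes it was -0.0292 and -0.0326, below the preset 0.01. The camera calls of that list ended with an estimated correlation as well, so a lost call does not by itself show correlated genes. A gene that was not above background on an array has only a bound there: the control mean against the higher of that array's lowest detected signal and the probe's own. Data were simulated with the spread of the controls and 200 of 13123 probes changed, by the same amount on both knockdown arrays. There the comparison of 2 with 3 arrays recovered 68.7% of changes of 1.5-fold, 94.0% of 2-fold and 100% of 4-fold, with 5 false calls. In the measured data the median residual SD, after moderation by eBayes, was 0.143 in the fit of 2 with 3 arrays and 0.107 in the fit of each siRNA. Recovery of shared changes by the comparison of 2 with 3 arrays may therefore be lower than simulated. In the same simulation the siTARBP2-1 array against the controls recovered 7.46%, 80.6% and 98.5%, with 6 false calls, and the siTARBP2-2 array 13.4%, 83.6% and 100%, with 12.

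Named genes were fixed by rule: Tarbp2, App and Zfp395; per direction the 12 largest changes among called genes whose knockdown arrays both lay beyond all controls, filled to 12 by smallest unadjusted p and then given as values only; up to 4 members per list by smallest unadjusted p; and 5 genes per direction for the contrast of the siRNAs. Alternatives were other background corrections (none, normexp with an offset of 50), median scaling, cyclic loess, the authors' series matrix and table, other filters, an intensity trend, robust eBayes, array quality weights, the replicate number as a block, each array left out, other gene summaries and thresholds, and each siRNA array normalized with the controls alone. Alternatives added after the files were seen were the detection column as deposited, a filter over 4 arrays, the mean of all probes beyond the main count, list tests for each siRNA, and each control array against the other 2.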

Results

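The experiment measured which transcripts change when TARBP2, a double-stranded RNA-binding partner of Dicer, is depleted in fibroblasts that have no Dicer. RNA taken 48 hours after transfection was profiled on 2 arrays with TARBP2 siRNAs and 3 arrays with control siRNA, and 8927 genes were above background. Control arrays differed from each other with an SD of the log2 difference of 0.173 to 0.212 across probes, siRNA arrays from controls with 0.306 to 0.346, and the TARBP2 siRNA arrays from each other with 0.387. The first principal component (44.8% of the variance) set siTARBP2-1 apart and the second (34.3%) siTARBP2-2.

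Tarbp2 itself was lower on both knockdown arrays. Probe ILMN_2939990 had a normalized log2 signal of 9.50, 9.55 and 9.36 on the control arrays, 7.67 with siTARBP2-1 and 7.18 with siTARBP2-2. Its level fell to 24.2% of control (log2 change -2.05, SE 0.16, n = 2 and 3; limma, adjusted p = 0.0412). Against control, siTARBP2-1 left 28.7% (limma, adjusted p = 0.0012) and siTARBP2-2 20.4% (adjusted p = 0.00129). The probe ILMN_2649955 had a log2 change of -1.84 (SE 0.23), which did not pass the test over both siRNAs (limma, adjusted p = 0.103), and fell with each of them, by 1.41 with siTARBP2-1 and by 2.26 with siTARBP2-2 on the log2 scale. Between the siRNAs, siTARBP2-1 minus siTARBP2-2, the difference in Tarbp2 did not pass the test for ILMN_2939990 (0.49; limma, adjusted p = 0.103) and passed it for ILMN_2649955 (0.85, adjusted p = 0.0212). The call on both siRNAs together ended without any 1 of the control arrays, with limma adjusted p-values of 0.489 without siControl-1, 0.407 without siControl-2 and 0.29 without siControl-3. It also ended with no filter (0.157), with the mean of all probes (0.0744) and with the replicate number as a block.

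**Figure D1:**
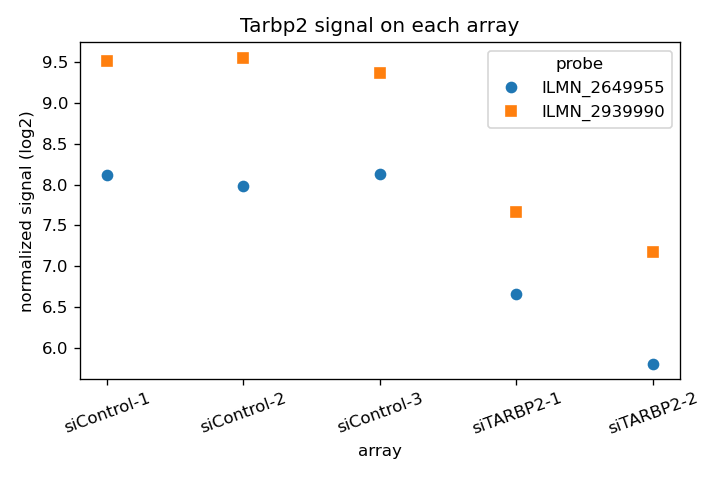
Normalized signal (log2, vertical axis) of the Tarbp2 probes on each array (horizontal axis), 1 point per probe and array. Probe ILMN_2939990 lies at 9.36 to 9.55 on the control arrays and at 7.67 and 7.18 on the TARBP2 siRNA arrays.

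Over both siRNAs together, Tarbp2 was the 1 gene that passed the test, and it was lower. The other genes named by rule did not pass it. Mmp13, a collagenase, had a log2 change of 1.19 (SE 0.11; limma, adjusted p = 0.0511), Pdgfb, a growth factor subunit, 1.26, Il24, a cytokine, 1.18, and Traf1, an adaptor of tumour necrosis factor receptors, 1.12. The higher genes by the same rule also held Zc3h6 (1.01), the thioredoxin-binding Txnip (0.89), Spef1 (0.87), the transcription factor Irf5 (0.85), Apobr (0.81), Rasl11b (0.80), the intermediate filament gene Nes (0.77) and the secreted chaperone Clu (0.75). Among the lower values that did not pass, the aldehyde dehydrogenase Aldh1a7 had -1.71 (SE 0.18; limma, adjusted p = 0.0901), the secreted glutathione peroxidase Gpx3 -0.97, the arachidonate lipoxygenase Alox12 -0.95 and the fatty acid elongase Elovl6 -0.92. Aldh1a7 was not above background with siTARBP2-1, where it was at least 3.86-fold lower than control. Other lower values were those of Igfbp5, an insulin-like growth factor binding protein (-1.15), the vasodilator peptide gene Adm (-1.03), Mal (-0.95), the lysophosphatidic acid receptor Lpar4 (-0.87), Bckdk (-0.84), Dtnb (-0.77) and the adenosine deaminase Ada (-0.72). App, the amyloid precursor protein gene, had -0.08 (SE 0.12; limma, adjusted p = 0.817), and Zfp395 was not above background; earlier work in human cancer cells names both as TARBP2 targets. At an unadjusted p under 0.05 limma gave 1152 genes, 614 higher and 538 lower, where 446 are expected by chance, and 3 genes had an adjusted p under 0.1. With no background correction 11 of the 24 changes named by rule were smaller by over 1.5 times and 0 turned, as for Mmp13, knockdown minus control, at 0.65 and Aldh1a7, knockdown minus control, at -0.94; with normexp and an offset of 50 it was 12 and with the series matrix values 11. The count of 1 became 11 with median scaling and 0 without any 1 of siControl-1, siControl-2 or siControl-3; with siTARBP2-1 or siTARBP2-2 left out it is the count of the other siRNA, given with that siRNA.

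Among the fixed gene lists, camera called 4 higher and 2 lower over both siRNAs, and 0 with an estimated correlation. Genes of the integrated stress response, the programme that follows phosphorylation of eIF2alpha, had a median log2 change of 0.23 over 34 genes (camera, adjusted p = 1.99e-06; adjusted p = 0.758 with an estimated correlation). Of these, 0 passed over all genes and 8 rose when adjusted over the list alone; the aminotransferase Gpt2 had 0.80, Ddit4 0.74, Ddit3 0.62 and Trib3 0.49. Cholesterol synthesis genes had a median of -0.38, with 20 of 21 negative (camera, adjusted p = 2.27e-07; adjusted p = 0.661 with an estimated correlation). None passed over all genes (0) and 3 fell when adjusted over the list alone, namely Scd2, a fatty acid desaturase (-0.65), and the sterol enzymes Dhcr7 (-0.59) and Cyp51 (-0.56). The p53 targets had a median of 0.20 (camera, adjusted p = 0.00025; adjusted p = 0.371 with an estimated correlation), with 0 called over all genes and 5 higher when adjusted over the list alone, such as Bbc3 at 0.72 and Cdkn1a at 0.46. NF-kB and secreted inflammatory genes had a median of 0.21 (camera, adjusted p = 0.000402; adjusted p = 0.371 with an estimated correlation), with 0 called over all genes and 3 higher when adjusted over the list alone, and the chemokine Cxcl1 at 0.67. That was the 1 list fry called (adjusted p = 0.0183). The interferon response list had 0.47 (camera, adjusted p = 4.76e-05; adjusted p = 0.877 with an estimated correlation) and DNA replication -0.09 (camera, adjusted p = 0.0255; adjusted p = 0.877 with an estimated correlation), with 0 genes of either called over all genes or adjusted over the list alone. Both turned when siTARBP2-1 was left out, to -0.27 and 0.06. The DNA replication call also ended without siControl-1 (camera, adjusted p = 0.0517) and with the mean of all probes (adjusted p = 0.0584), and the stress response call without siTARBP2-2 (camera, adjusted p = 0.0774).

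With siTARBP2-1 against control, interferon response genes rose together. Of 41 measured members 33 rose and 0 fell over all genes, and 38 rose and 1 fell when adjusted over the list alone, with a median log2 change of 1.19 (camera, adjusted p = 1.23e-30; adjusted p = 0.298 with an estimated correlation; fry, adjusted p = 0.033). The interferon-induced chemokine Cxcl10 rose by 2.29 (SE 0.11; limma, adjusted p = 0.000966), the nucleotide kinase Cmpk2 by 2.32, the antiviral GTPase Mx2 by 2.26 and Ifit3, an RNA-response gene, by 2.24. These genes were above background in control as well; Ifit3 had a control log2 signal of 11.57 ± 0.0789 (SD, n = 3). The double-stranded RNA-binding genes Adar and Eif2ak2, also known as interferon-responsive, rose by 1.09 and 0.62. On the same array DNA replication genes had a median of -0.26 (camera, adjusted p = 4.42e-05; adjusted p = 0.298 with an estimated correlation; fry, adjusted p = 0.00627). Of 31 members 4 fell over all genes and 6 when adjusted over the list alone, among them the thymidine kinase Tk1 (-0.74) and the cyclin Ccne1 (-0.64). G2/M genes had a median of -0.16 (camera, adjusted p = 0.0214; adjusted p = 0.681 with an estimated correlation), with 2 lower over all genes and 3 adjusted over the list alone, the centromere histone Cenpa at -0.83 and Foxm1 at -0.63. The p53 targets had 0.17 (camera, adjusted p = 0.00293; adjusted p = 0.654 with an estimated correlation), with 5 higher over all genes and 8 adjusted over the list alone; they held the cell death gene Bbc3 (1.00) and the peptide transporter Tap1 (0.93), which is known to respond to interferon. Cholesterol synthesis had -0.19 (camera, adjusted p = 0.0399; adjusted p = 0.488 with an estimated correlation), where Scd2 fell by 0.58 on the log2 scale as the 1 member called over all genes and the 1 adjusted over the list alone. NF-kB and secreted inflammatory genes had 0.18 (camera, adjusted p = 0.0344; adjusted p = 0.488 with an estimated correlation), with 3 higher and 1 lower over all genes and 4 and 1 adjusted over the list alone; Mmp13 rose by 1.23, and the chemokine Cxcl12 fell (-2.12). Fry did not call the G2/M, p53 and cholesterol lists (adjusted p = 0.141 each) or the NF-kB list (adjusted p = 0.0558). The NF-kB camera call also ended under 6 other settings, among them no background correction, and the cholesterol call for probes detected on all 5 arrays. Single control arrays against the other controls had medians of -0.05 to 0.07 for G2/M genes and -0.09 to 0.03 for p53 targets. For cholesterol synthesis these control medians were -0.04 to 0.12, and for NF-kB and secreted inflammatory genes -0.06 to 0.01. The number of genes called for siTARBP2-1 against control by limma was 683, 346 higher and 337 lower. That count was 255 without siControl-2, 435 with no filter and 1220 with no background correction, and with median scaling it split into 248 higher and 571 lower, beside a shift of the median of all genes of -0.12. Of 62 named calls, 29 ended without siControl-2, and 15 had values smaller by over 1.5 times with no background correction, where the median of the cholesterol synthesis list, siTARBP2-1 minus control, was -0.10.

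With siTARBP2-2 against control, some cholesterol synthesis genes fell (6 of 21 over all genes) and some integrated stress response genes rose (8 of 34). Cholesterol synthesis genes had a median log2 change of -0.52, with 0 of 21 positive (camera, adjusted p = 9.35e-10; adjusted p = 0.328 with an estimated correlation; fry, adjusted p = 0.0385). Of these 6 fell over all genes and 14 when adjusted over the list alone, including the fatty acid desaturases Scd1 (-0.82, SE 0.11; limma, adjusted p = 0.0212) and Scd2 (-0.72) and the sterol enzymes Hsd17b7 (-0.80) and Sc5d (-0.76). Integrated stress response genes had a median of 0.38 (camera, adjusted p = 9.35e-10; adjusted p = 0.506 with an estimated correlation; fry, which did not call it, adjusted p = 0.11), and 8 of 34 rose over all genes and 18 when adjusted over the list alone. Vldlr, a lipoprotein receptor, rose by 1.17, Gpt2 by 1.00, the folate enzyme Aldh1l2 by 0.93 and the stress transcription factor Ddit3 by 0.86. Interferon response genes had a median of -0.27 (camera, adjusted p = 4.39e-05; adjusted p = 0.506 with an estimated correlation). Of 41, 0 rose and 4 fell over all genes, with 1 and 10 adjusted over the list alone; those that fell were the RNA helicase Dhx58, which fell by 1.00 on the log2 scale, Oasl1 (-0.94), the chemokine Ccl5 (-0.67) and Ifit3 (-0.59). Hypoxia and glycolysis genes had -0.16 (camera, adjusted p = 0.0217; adjusted p = 0.506 with an estimated correlation), where 1 rose and 3 fell over all genes, and 1 and 7 adjusted over the list alone; the glycolytic enzymes Ldha and Aldoa had -0.57 and -0.64. The p53 targets had 0.18 (camera, adjusted p = 0.00953; adjusted p = 0.506 with an estimated correlation), with 1 higher over all genes, Gadd45a (1.12), and 5 adjusted over the list alone. NF-kB and secreted inflammatory genes had 0.23 (camera, adjusted p = 0.00931; adjusted p = 0.506 with an estimated correlation; fry, adjusted p = 0.0363), with 2 higher over all genes, Mmp13 (1.15) and the NF-kB subunit Relb (0.73), and 7 higher and 1 lower adjusted over the list alone. Fry did not call the interferon (adjusted p = 0.216), hypoxia (0.129) or p53 lists (0.167). The number of genes called for siTARBP2-2 against control by limma was 381, 156 higher and 225 lower. The count was 57 without siControl-2, 240 without siControl-3, 83 with no filter and 955 with no background correction. Of 51 named calls, 34 ended without siControl-2 and 30 with no filter, and 13 had values smaller by over 1.5 times with no background correction.

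**Figure D2:**
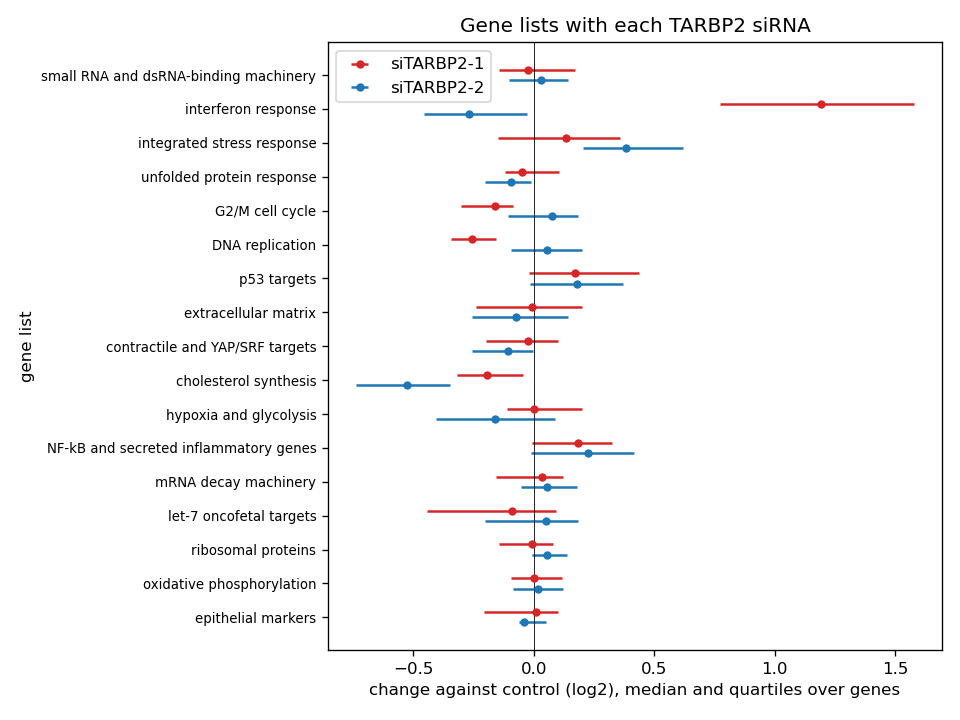
Change against control (log2, horizontal axis) of each fixed gene list with at least 5 measured genes (vertical axis), as the median over genes with bars from the lower to the upper quartile, for siTARBP2-1 (red) and siTARBP2-2 (blue). The interferon response list lies at 1.19 with siTARBP2-1 and at -0.27 with siTARBP2-2.

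Set against each other, the TARBP2 siRNAs had their largest median difference, of the 17 lists tested, in interferon response genes. That list was higher with siTARBP2-1 by a median log2 difference of 1.38 (camera, adjusted p = 2.02e-30; adjusted p = 0.28 with an estimated correlation; fry, adjusted p = 0.0344), with 31 of 41 members higher over all genes and 37 adjusted over the list alone. By the smallest p, the secreted protease-like Prss35 (3.21, SE 0.14; limma, adjusted p = 0.000855), Cxcl10 (2.76), Ifit3 (2.83), Dhx58 (2.19) and Cmpk2 (2.76) were higher with siTARBP2-1. The linker histone H1f10 (-2.19), the stathmin Stmn2 (-3.02), the matrix protein gene Smoc1 (-1.92), Nme7 (-1.81) and the membrane glycoprotein gene Gpnmb (-1.74) were lower. The kept Gpnmb probes did not all move the same way. Against control, Prss35 rose by 0.99 with siTARBP2-1 and fell with siTARBP2-2 (-2.22), and Stmn2 fell with siTARBP2-1 (-1.79) and rose with siTARBP2-2 (1.23). Cholesterol synthesis (0.33) and hypoxia and glycolysis (0.25) were higher with siTARBP2-1 (camera, adjusted p = 0.000603 and 0.0194; adjusted p = 0.28 and 0.596 with an estimated correlation). Integrated stress response (-0.31), DNA replication (-0.32) and G2/M genes (-0.23) were lower (camera, adjusted p = 0.00236, 0.000603 and 0.00893; adjusted p = 0.69, 0.28 and 0.596 with an estimated correlation). Fry called the DNA replication list (adjusted p = 0.0114) but not the cholesterol (0.0663), hypoxia (0.128), stress response (0.217) or G2/M lists (0.115). The number of genes called between the 2 TARBP2 siRNAs by limma was 630, 332 higher with siTARBP2-1 and 298 lower. The count was 268 without siControl-2, 381 with no filter and 1260 with no background correction, and median scaling split it into 266 higher and 630 lower, beside a shift of the median of all genes of -0.15.

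A smaller group of genes changed the same way with both siRNAs. Limma called 78 genes in the same direction, 33 higher and 45 lower, where independent lists of these sizes share 14.5 (6.05 higher and 8.49 lower), and 19 in opposite directions, where independent lists give 14.6. The 24 genes named for both siRNAs together were among the 78, but the choice by the smallest p over both favours such genes, so this is no independent evidence of shared changes. Mmp13, Il24 and Traf1 rose and Aldh1a7, Gpx3 and Elovl6 fell with each siRNA. Across genes, which are not independent replicates, the log2 changes of the siRNAs had a Pearson correlation of 0.202 and a Spearman correlation of 0.206. Simulated arrays with no effect that share the controls gave 0.251 and 0.238. Simulated unrelated effects of the called genes, with the controls shared, gave a Pearson correlation of 0.0784 (at most 0.109 in 100 draws) and a Spearman correlation of 0.188 (at most 0.211). The Pearson correlation was thus above the draws with unrelated effects and below the mean with no effect, and the Spearman correlation was within the range of the former. The covariance was 0.0193, against 0.00462 with no effect and 0.00467 with unrelated effects (at most 0.00639), and 56.6% of genes had the same sign, against 58.1% and 57.2%. The controls are too few to split, so part of the excess in shared calls may come from the shared controls. For the agreement of the 2 TARBP2 siRNAs, the count of 78 was 14 without siControl-2, 17 with no filter and 202 with no background correction.

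**Figure D3:**
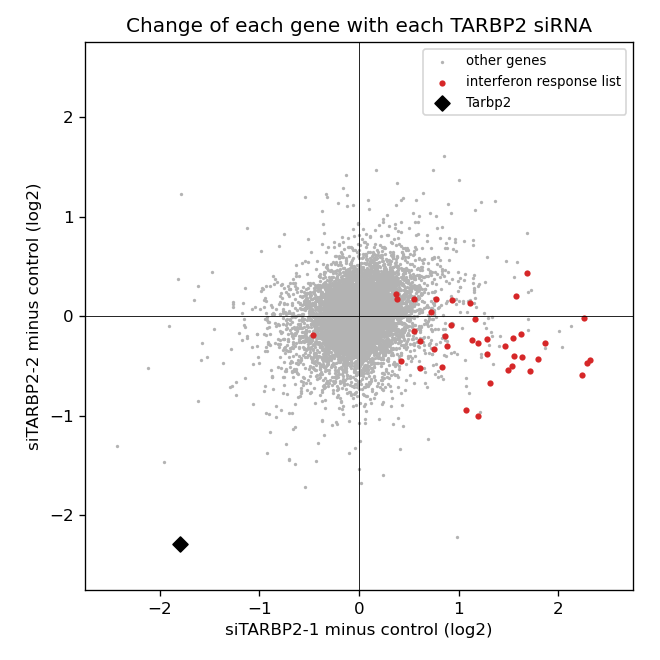
Log2 change against control of each of 8927 genes with siTARBP2-1 (horizontal axis) and with siTARBP2-2 (vertical axis), 1 point per gene, with the interferon response list in red and Tarbp2 as a black diamond. Tarbp2 lies at -1.80 and -2.29, and most interferon genes lie to the right of 0 on the horizontal axis only.

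Markers of other cell types were mostly at background. Of the 6 macrophage genes on the array 2 were above it, and limma called 0 over all genes with either siRNA; adjusted over the list alone, 1 was lower with siTARBP2-1 and 1 higher with siTARBP2-2. The macrophage marker Cd14 had -0.46 with siTARBP2-1 and 0.33 with siTARBP2-2 (limma, adjusted p = 0.0602 and 0.151) and was lower with siTARBP2-1 than with siTARBP2-2 by the test of the difference (-0.79, adjusted p = 0.0233). Lyz2, an abundant macrophage transcript, was not above background on any array. The 6 endothelial genes had 0 kept. Of 5 epithelial, 2 skeletal muscle and 2 adipocyte genes kept, 0 were called over all genes with either siRNA by limma. When adjusted over the list alone, 1 epithelial gene was higher with siTARBP2-2, 1 skeletal muscle gene was lower with each siRNA, and 1 adipocyte gene was higher and 1 lower with siTARBP2-2. Of 4 neural genes kept, Nes rose with siTARBP2-1 (0.87) and siTARBP2-2 (0.68), as the 1 member called with each over all genes and adjusted over the list alone. Another kept Nes probe, of lower signal, had 0.26 and 0.16 and was called with neither.

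The authors' deposited table marks 1625 of its 18744 accessions as higher after knockdown, and the lowest marked log2 fold change in the authors' deposited table was 0.10, a fold of 1.07. Of 1086 marked accessions with exactly 1 probe, 883 (81.3%) were higher with both siRNAs in the deposited intensities, 110 with siTARBP2-1 alone and 93 with siTARBP2-2 alone. Of all 12070 accessions with exactly 1 probe, 30.1% were higher with both. The marks follow a change taken over both siRNAs against the same controls, so a high share is built in and does not show that the siRNAs act alike. For Tarbp2 the authors' deposited table gives -1.19.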

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

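The tests of Tarbp2 loss, of the siTARBP2-1 sequence, of knockdown depth and of features common to the TARBP2 siRNA samples were chosen after the results were seen; the test of control arrays against each other was added after the files were seen and before its result. The effects of the TARBP2 siRNAs against the same controls differed by a direct limma test in 630 genes, and by camera in 6 lists. The list medians, siTARBP2-1 minus siTARBP2-2 on the log2 scale, were 1.38 for interferon response, 0.33 for cholesterol synthesis, 0.25 for hypoxia and glycolysis, -0.31 for the integrated stress response, -0.23 for G2/M and -0.32 for DNA replication. The list calls all ended with an estimated correlation, where the few residual degrees of freedom let hardly any list pass. Single genes with a called difference were Prss35 (3.21), Ifit3 (2.83), Cxcl10 (2.76), Cmpk2 (2.76), Dhx58 (2.19), Stmn2 (-3.02), H1f10 (-2.19), Smoc1 (-1.92), Nme7 (-1.81) and Gpnmb (-1.74). The 3 kept Gpnmb probes did not all move the same way.

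Interferon response genes were higher with siTARBP2-1 and not with siTARBP2-2. Loss of Tarbp2 as the whole cause is argued against by the siTARBP2-2 array, where Tarbp2 had also fallen against control (-2.29) and the list's median was -0.27, while the control arrays had medians of -0.17, 0.13 and 0.05, each against the other 2 controls. RNA of macrophages is argued against by the 0 of 3 probes of Lyz2, an abundant macrophage transcript, above background there; the median over 13 macrophage probes was -0.0123, but 10 of these were above background on no array, so only a rise could show in them. The sequence of siTARBP2-1 and an event in its sample cannot be told apart, because 1 array carries that siRNA. An effect of siTARBP2-1 outside its target, or Tarbp2 loss acting only with some other condition, may remain as hypotheses, and neither was tested.

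Most genes called with one TARBP2 siRNA were not called with the other: 586 of the 683 called with siTARBP2-1 were not called with siTARBP2-2. A gene not called is not shown to be unchanged, since the siTARBP2-2 array recovered 13.4% of simulated changes of 1.5-fold. Array-to-array spread as among the controls is argued against by the 0 genes that limma called for siControl-1, siControl-2 or siControl-3 against the other 2 controls (876, 188 and 398 at an unadjusted p under 0.05); with 2 controls left, the number of genes called for siTARBP2-1 against control was 255 to 800, and the number of genes called for siTARBP2-2 against control was 57 to 501. For the changes with siTARBP2-1, a difference in knockdown depth as the whole cause is argued against by the slope of the siTARBP2-2 changes on them. Over all kept genes, with the noise of the control arrays taken out, it was 0.159 (95% interval over genes drawn anew 0.124 to 0.195). At least 1 is needed if Tarbp2 is no higher with siTARBP2-2, which both probes show and 1 of them by a limma call. It is also assumed that changes do not shrink as Tarbp2 falls and that its RNA stands for its protein, and neither was measured. Any variation of the siTARBP2-1 array beyond that between controls would lower the slope. The slope uses the same changes as the correlation above, so it is no separate evidence. Its interval draws genes, which are not independent replicates, and each siRNA has 1 array. A part played by depth beside effects particular to siTARBP2-1 is not excluded. For the genes called with siTARBP2-2, of which 303 were not called the same way with siTARBP2-1, depth stays open. Counted in the direction called with siTARBP2-2, their median log2 change was 0.17 with siTARBP2-1 (quartiles -0.0925 and 0.434) and 0.73 with siTARBP2-2. A response may need a lower Tarbp2 level. Effects particular to each siRNA or to each sample stay open and could not be separated with 1 array each.

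More genes were called the same way with both siRNAs (78) than independent lists give. With the called effects of siTARBP2-2 placed anew among genes and the controls shared, the highest of 100 simulated draws was 29. For effects placed in this way, the draws argue against the shared controls as the whole source. The draws left out effects too small to be called. They also placed effects without regard to each gene's spread between the controls, though genes with a low spread pass more easily with both siRNAs. Loss of Tarbp2 and any other feature common to the TARBP2 siRNA samples cannot be told apart for these 78 genes, since no array with restored Tarbp2 is in the design. A role of Tarbp2 loss in them may therefore be put forward only as a hypothesis.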

How the results depend on the processing

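The detection column as deposited, the filter over 4 arrays, list tests for each siRNA and the mean of all probes beyond the main count were chosen after the data were seen; the cause of each change below was not tested. The count over both siRNAs (1) became 11 with median scaling (4 higher and 7 lower), 3 with cyclic loess, 3 at an adjusted p under 0.1, 2 for probes detected on all 5 arrays, and 0 with no filter or with the mean of all probes; leaving out 1 array gave 0 to 683. The Tarbp2 level lost its limma call at -2.05 with no filter and -1.94 with the mean of all probes, and was -1.19 in the authors' table; leaving out 1 array gave -2.29 to -1.80. The genes called for siTARBP2-1 against control (683), genes called for siTARBP2-2 against control (381), genes called between the 2 TARBP2 siRNAs (630) and agreement of the 2 TARBP2 siRNAs (78 called the same way) became 1220, 955, 1260 and 202 with no background correction, 1225, 952, 1268 and 201 with normexp and an offset of 50, 1221, 955, 1248 and 201 with the series matrix values, 435, 83, 381 and 17 with no filter and 1218, 934, 1234 and 194 with an intensity trend. For probes detected on all 5 arrays the last 3 were 654, 948 and 140. Leaving out 1 array gave 255 to 800, 57 to 501, 268 to 932 and 14 to 96. Of 6 lists called over both siRNAs 0 held with an estimated correlation and 1 with fry. The interferon difference of 1.38 lost its call with an estimated correlation. Because of the few residual degrees of freedom, calls lost with an estimated correlation decide little. Without siTARBP2-1 the interferon list over both siRNAs turned to -0.27 and DNA replication to 0.0558; leaving out 1 array gave up to 1.19 for the first and down to -0.26 for the second. Without siControl-2, 29 of 62 named calls with siTARBP2-1 and 34 of 51 with siTARBP2-2 ended, and 0 turned; with no filter 8 and 30 ended. With other settings apart from leaving out an array, the list tests named above included, 903 list values kept their call or lack of one. Of the other list values 49 lost the call, 3 gained it and 5 moved. Of the named genes' values 3777 kept theirs, 64 lost the call, 220 gained it and 59 moved. Values called in neither setting count as kept even where the sign turned. Values of the authors' table, which has no test, count as kept or moved by size alone.

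The knockdown and control arrays share replicate numbers 1 and 2. Deviations of same-numbered arrays from their group means had correlations of -0.0485 and -0.0266. With 2 knockdown arrays these deviations mirror each other and hold the difference between the siRNAs. They therefore cannot show whether the numbers pair the arrays. With the replicate number as a block, 0 genes were called over both siRNAs and the Tarbp2 level was -2.10 (limma, adjusted p = 0.164). The block and the array weights could not be fitted for single siRNAs, and the slide was not run as a block because the files give none.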

Other observations

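The genes in this paragraph outside the fixed lists were chosen after their values were seen, and no enrichment was tested among them. Of 36 extracellular matrix genes, 2 rose and 5 fell with siTARBP2-1 over all genes (5 and 7 adjusted over the list alone), and 0 and 4 with siTARBP2-2 (1 and 5 adjusted over the list alone), while camera called the list with neither (adjusted p = 0.917 and 0.254). The collagen gene Col1a1 fell with each (-0.65 and -0.55), as did the basement membrane gene Nid2 (-0.64 and -1.12), the Wnt pathway genes Rspo2 (-0.71 and -1.45), Sfrp2 (-0.87 and -0.61) and Dkk3 (-0.86 and -0.73), and Spon2 (-2.43 and -1.30). Higher with each were the chemokine Cxcl16 (0.64 and 1.24) and Nlrc5, a regulator of antigen presentation genes (0.84 and 0.90). Of the 19 called in opposite directions, Tlr3, a receptor for double-stranded RNA, had 1.08 with siTARBP2-1 and -0.70 with siTARBP2-2, and Ifi27l2a 1.21 and -0.96.

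The other lists were called by camera neither over both siRNAs nor with either. Their median log2 changes with siTARBP2-1 and siTARBP2-2 were -0.01 and -0.07 for extracellular matrix, -0.05 and -0.10 for the unfolded protein response, -0.02 and -0.11 for contractile and YAP/SRF targets, 0.03 and 0.05 for mRNA decay, -0.09 and 0.05 for let-7 targets, -0.01 and 0.05 for ribosomal proteins, 0.00 and 0.02 for oxidative phosphorylation and 0.01 and -0.04 for epithelial markers. The small RNA and double-stranded RNA-binding machinery had -0.02 and 0.03, with Tarbp2 lower and Adarb1, an RNA-editing enzyme, higher with siTARBP2-2 (0.75). Some lists were called with one siRNA and not with the other. The integrated stress response had 0.13 with siTARBP2-1 (camera, adjusted p = 0.0774) and hypoxia and glycolysis 0.00 (adjusted p = 0.897). With siTARBP2-2, DNA replication had 0.06 (camera, adjusted p = 0.734) and G2/M genes 0.08 (adjusted p = 0.58).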
